A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

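Total RNA from Saccharomyces cerevisiae was hybridised to 18 one-colour Affymetrix YG_S98 arrays in 8 genotype groups. The groups were wild type (n = 3), the deletion of RPD3, which encodes a histone deacetylase (n = 2), a deletion of histone H3 residues 1 to 28 (n = 2), a histone H3 with lysines 4, 9, 14, 18, 23 and 27 changed to glutamine (n = 3), a deletion of histone H4 residues 2 to 26 (n = 2), a histone H4 with lysines 5, 8, 12 and 16 changed to glutamine (n = 2), and 2 double mutants that joined the RPD3 deletion to the H3 tail deletion (n = 2) or to the H4 lysine substitution (n = 2). Growth conditions, and whether arrays of a group came from separate cultures, are not given in the sources used here. The number of arrays per group limits the precision of every value.

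The deposited table holds an intensity per probe set on a linear scale in arbitrary units, from 0 to 107107.3, with 1 column per array. The authors had scaled each array to a common 2% trimmed mean, as seen in the values, whose trimmed means ran from 1501 to 1502 while array medians ran from 387.1 to 545.0. The probe-level summary and its software are not given in the sources used here. Per the file headers, the array run settings, whose unit is other than a measurement, held an array type for all arrays and, for 17 of 18, a chip lot and a description. These settings and the sampling days in the labels were used as batches, called day A to day H and lot a to lot d. Days A to D formed an earlier and days E to H a later sampling period.

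The rule on scale, fixed in advance, was to use the table as deposited only if array medians and trimmed means both differed by less than 1.1 times. They did not, so each array was scaled to the common 2% trimmed mean, which left the deposited values nearly as they were. Signals below the pooled 25th percentile (140.2) were set to it, and probe sets above it on at least 2 arrays were tested. Of 9335 probe sets, 60 controls were left out. Of the rest, 6504 named 1 gene, 328 named several genes and 2443 had no gene symbol. The probe annotation was matched by gene identifier to the R64 gene table for all 6504, which stood for 5656 genes. The tests covered 7851 probe sets, of which 6080 named 1 gene (5447 genes). Genes named only together with others on their probe sets, such as HHT1, HHT2, HHF1 and HHF2, which encode H3 and H4, were not read as single genes.

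Differences were tested with limma 3.58.1 in R 4.3.3 on log2 signals. All 18 arrays entered 1 fit with a mean per group (10 residual degrees of freedom), a trended empirical Bayes variance (3.76 prior degrees of freedom) and Benjamini-Hochberg adjustment within each of 13 contrasts at 0.05. All tests were two-sided. The contrasts were each mutant against wild type, each double mutant against its histone mutant, 2 interactions (whether the effect of deleting RPD3 differed with and without the histone mutation) and each tail deletion against the lysine substitution of the same histone. Standard errors of log2 changes are limma's, and errors of mean signals are standard deviations over the arrays of the group. The p-values measure the spread between these arrays, which may be technical. Both arrays of the H4 lysine substitution and both of its double mutant were from day E. The first and second arrays of the H3 lysine substitution were from day F. The pooled spread thus leaves out part of the variation between days, and p-values against wild type, from other days, can be too small. In a test on simulated data, 4-fold changes put into 200 probe sets were called in 94%, 2-fold changes in 49% and 1.5-fold changes in 0.5% with 2 arrays against 3. A simulated shift of the later sampling period, of arbitrary size, gave 1361 false calls for the H3 lysine substitution against wild type, and 0 with a block for period.

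Gene lists were fixed before the data were examined, as were the comparisons, the filter, the floor and the rule for named genes. Of 38 lists, 36 had members to test as a set, among them the outermost 10 tested genes of each of 32 chromosome arms. Counts of list members leave out members that did not pass the filter. Ranks from a chromosome end pass over genes not named alone on a tested probe set. A silent end gene thus has a rank only if it was above the floor on at least 2 arrays. Lists were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a contrast. A call of a list at the preset correlation held with an estimated correlation in 5 of 174 cases. These were the alpha-specific genes in the RPD3 deletion, the H4 tail deletion, the H3 double mutant and the 2 H4 mutants compared, and the haploid-specific genes in the H4 tail deletion.

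The named genes were, per contrast against wild type, the 8 largest rises and the 8 largest falls among called probe sets for 1 gene whose arrays did not overlap between groups and whose higher group was above the floor on every array. For other contrasts they were the 4 largest each way. To these were added RPD3, the silent mating-type gene HMRA1, and up to 4 members of each called list with the smallest adjusted p. No H3 or H4 gene and no other silent mating-type gene could be added, since none was tested as a single gene. A gene at the floor on all arrays of a group is given as a lower bound of its fold with the measured means. Where some arrays of a group were at the floor, the fold was computed with these arrays at the floor and can be smaller than the ratio of the printed means.

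Alternatives were quantile normalization, median centring of arrays, no filter with a floor at the 5th percentile, a floor at the 40th percentile, leaving out each array, blocks for replicate number, for sampling day (fixed or random) and for sampling period, and the actin 3' to 5' ratio as a covariate. Days C and H held no array other than wild type, so with day as a fixed block wild type entered comparisons through its day B array alone. With a block for period, or for chip lot, groups of the later period were compared with the third wild-type array alone. The header of the first H4 tail deletion array gave no chip lot, so that block counts this group through its second array alone. A block for chip lot, a fit without 3 arrays whose header named another strain than the label, and the use of different wild-type arrays in correlated comparisons were chosen after seeing the data. Overlaps between contrasts that share the wild-type arrays were set beside 50 simulations in which no group had changed and every array, wild type included, was drawn anew. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.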

Results

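The arrays were compared to ask which yeast genes depend on the histone deacetylase Rpd3, on the amino-terminal tails of histones H3 and H4, and on the lysines of those tails. RPD3 signal was 1001, 959.2 and 689.9 on the 3 wild-type arrays, a mean of 883.5 ± 169 (SD, n = 3). It was 25.8 and 9.4 in the RPD3 deletion, 30.2 and 65 in the double mutant with the H3 tail deletion, and 70.1 and 80.7 in the double mutant with the H4 lysine substitution. All 6 of these arrays were under the floor of 140.2, so that RPD3 was at least 6.22-fold lower than in wild type in each of the 3 groups. Signals in the histone mutants with intact RPD3 were 693.6 and 974.3 (H3 tail deletion), 728.2, 799 and 685.5 (H3 lysine substitution), 519.1 and 493.6 (H4 tail deletion) and 608.1 and 719.7 (H4 lysine substitution). Of these 4 groups, the H4 tail deletion had a called difference from wild type in RPD3, with a log2 change of -0.78 ± 0.21 (adjusted p = 0.0138).

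Arrays of 1 group correlated at 0.949 to 0.988 across probe sets, and arrays of different groups at 0.870 to 0.970. The headers of 3 arrays, the second replicate of the H3 tail deletion, of the H4 tail deletion and of the H3 double mutant, named another strain than their labels. The first and second of these correlated best with their labelled group (0.977 against 0.962 for the next group, and 0.982 against 0.955). The H3 double mutant array was by group mean also closest to its label (0.958 against 0.956), by a small margin, and correlated at 0.966 with the second array of the H3 lysine substitution. The header of the third wild-type array was the 1 header that named an RNA amplification kit. Wild-type arrays were taken on days B, C and H. No array of the H3 lysine substitution, the H4 tail deletion, the H4 lysine substitution or the H4 double mutant shared a day with wild type, so that day could not be separated from genotype within any day in these comparisons.

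**Figure D1:**
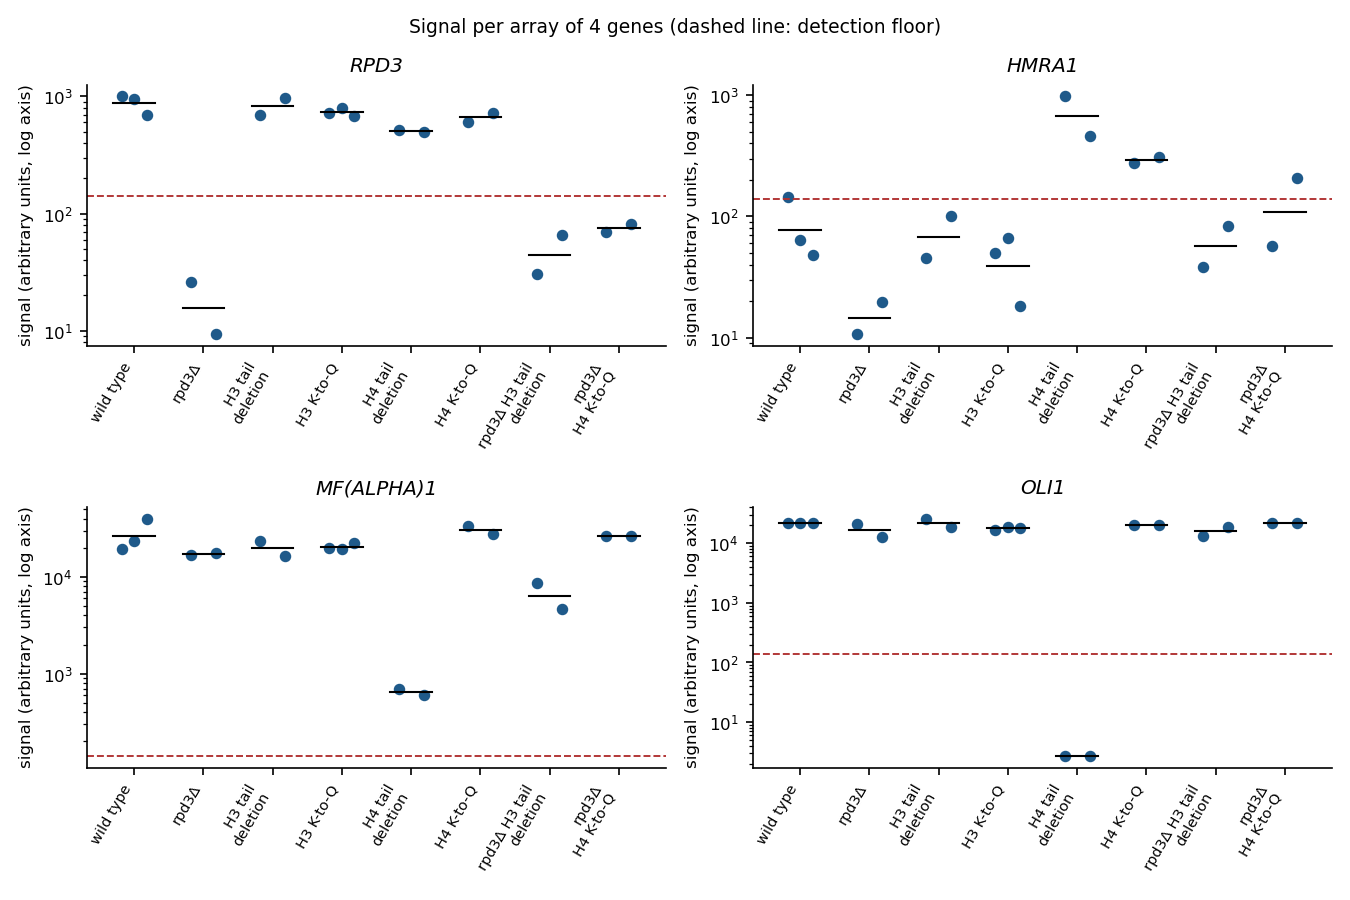
Signal per array (points, log axis, arbitrary units) of RPD3, HMRA1, MF(ALPHA)1 and OLI1 in the 8 groups, with the geometric mean of each group (bars) and the floor of 140.2 (dashed). RPD3 lies below the floor in all 6 arrays with the RPD3 deletion, and OLI1 reads 2.7 on both arrays of the H4 tail deletion.

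In the RPD3 deletion, INO1, which encodes inositol-3-phosphate synthase, rose 11.3-fold to 8528 ± 986 from 787 ± 277 (SD, n = 2 and 3), a log2 change of 3.50 ± 0.35 with an adjusted p = 4.32e-05. OPI3, a phospholipid methyltransferase gene, rose 9.20-fold (3.20 ± 0.37, adjusted p = 0.000106), and COX5B, the hypoxic isoform of a cytochrome oxidase subunit, rose 10.2-fold (3.36 ± 0.36). The alpha-factor gene MF(ALPHA)2 fell 25.8-fold to 574 ± 369 from 13503 ± 3879 (log2 change -4.69 ± 0.48, adjusted p = 4.47e-05), the alpha-agglutinin gene SAG1 fell 10.1-fold and the a-factor receptor gene STE3 fell 6.36-fold. GSP2, CRG1, GTT1, UGX2 and SDP1 completed the 8 largest rises (log2 changes of 3.30, 3.14, 2.99, 2.88 and 2.85). AGA1, RSC8, SST2 and FUS1 were among the largest falls (-3.05, -2.82, -2.69 and -2.67).

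Of 5 alpha-specific genes, which only cells of the alpha mating type express, 4 fell and 1 was not called, the same count adjusted over the list alone, with a median log2 change of -2.67 (camera adjusted p = 1.19e-08, and adjusted p = 0.0431 with an estimated correlation). Of 29 early meiotic genes with a probe set of their own, 22 passed the filter, and the others were above the floor on fewer than 2 arrays. Among the 22 tested, 13 rose, 1 fell and 8 were not called, with the same counts adjusted over the list alone (median 0.61, adjusted p = 6.07e-07, and adjusted p = 0.124 with an estimated correlation). DMC1, the meiotic recombinase gene, rose by 2.33 ± 0.27 on the log2 scale. HOP1, a chromosome axis gene, was at the floor on every wild-type array and rose at least 3.09-fold, with means of 439 and 97.9. Of 16 phospholipid and inositol genes 6 rose and 10 were not called, with 7 rises adjusted over the list alone (median 0.63, adjusted p = 0.00302, and adjusted p = 0.218 with an estimated correlation). CHO1, the phosphatidylserine synthase gene, changed by 1.11 ± 0.22. General stress genes rose in 16 of 37 cases with none lower, or 24 adjusted over the list alone (median 1.01, adjusted p = 3.34e-09, and adjusted p = 0.477 with an estimated correlation). Of 6 genes of the subtelomeric COS family 4 fell and 2 were not called, also adjusted over the list alone (median -0.89, adjusted p = 9.99e-05, and adjusted p = 0.218 with an estimated correlation), among them COS7 (-1.91 ± 0.26) and COS8 (-1.75 ± 0.35). Ribosome biogenesis and RNA polymerase I genes fell in 14 of 74 cases, 15 adjusted over the list alone, with a median of -0.37 (adjusted p = 2.57e-09, and adjusted p = 0.511 with an estimated correlation).

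The RPD3 deletion changed 1207 of 7851 probe sets, 883 higher and 324 lower, of which 502 and 172 changed at least 2-fold. The split was 751 higher and 471 lower under quantile normalization and 668 higher and 519 lower under median centring. With the day as a block, where wild type counts through its day B array alone, 472 probe sets were called, and the medians were -2.54 for the alpha-specific, 0.63 for the early meiotic and 0.55 for the stress genes. Without the second RPD3 deletion array 520 were called. The actin 3' to 5' ratio was 1.68 and 1.66 on the RPD3 deletion arrays and 1.37 to 1.41 in wild type. With this ratio as a covariate 742 were called, 630 higher and 112 lower.

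Cells with the H3 tail deletion had raised RTC3, a stress-linked gene, by 9.83-fold to 2549 ± 205 from 276 ± 138 (SD, n = 2 and 3; log2 change 3.30 ± 0.35, adjusted p = 0.000148). CYC7, the hypoxic isoform of cytochrome c, rose 8.68-fold (3.12 ± 0.41), GOR1 7.46-fold (2.90 ± 0.22) and the hexose transporter gene HXT4 6.88-fold (2.78 ± 0.53). MF(ALPHA)2 fell 11.03-fold (-3.46 ± 0.48, adjusted p = 0.000588), SAG1 6.00-fold (-2.59 ± 0.32), the cell-cycle arrest gene FAR1 4.84-fold (-2.27 ± 0.26) and SST2, a regulator of pheromone signalling, 4.57-fold (-2.19 ± 0.26). SRX1, YNR064C, CMI8 and PET117 rose by 2.65 to 2.69.

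Of 5 alpha-specific genes 4 fell, the same adjusted over the list alone (median -1.94, adjusted p = 3.38e-07, and adjusted p = 0.095 with an estimated correlation). General stress genes rose in 28 of 37 cases and 9 were not called, with 32 rises adjusted over the list alone (median 1.36, adjusted p = 1.09e-16, and adjusted p = 0.219 with an estimated correlation). Examples were GLC3, a glycogen branching enzyme gene (2.39 ± 0.36), and TFS1 (2.34 ± 0.33). Of 27 glucose-repressed and gluconeogenic genes 17 rose and 10 were not called, with 20 rises adjusted over the list alone (median 1.21, adjusted p = 3.28e-09, and adjusted p = 0.205 with an estimated correlation), among them SFC1, POT1 and FOX2 (1.97, 1.82 and 1.59). All 10 tested PAU genes, a family of cell-wall seripauperins, rose, also adjusted over the list alone (median 0.95, adjusted p = 8.58e-08, and adjusted p = 0.219 with an estimated correlation). Ribosome biogenesis and RNA polymerase I genes fell in 17 of 74 cases, 33 adjusted over the list alone (median -0.54, adjusted p = 1.09e-16, and adjusted p = 0.264 with an estimated correlation). Of 6 COS genes 4 rose, 5 adjusted over the list alone (median 1.04, adjusted p = 0.0046, and adjusted p = 0.323 with an estimated correlation).

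The H3 tail deletion changed 1071 probe sets, 837 higher and 234 lower. This split was 723 and 425 under quantile normalization and 644 and 440 under median centring. A block for the day, again with 1 wild-type array, left 290 calls and list medians of -1.79 for alpha-specific, 1.01 for stress and 0.70 for glucose-repressed genes. The count was 431 without the second and 673 without the first H3 tail deletion array, and 455 without the 3 arrays whose headers named another strain. The actin 3' to 5' ratio was 1.85 on the first array, the highest of all arrays, and 1.44 on the second, and with it as a covariate 829 were called, 676 higher and 153 lower.

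With H3 lysines changed to glutamine, DPI8 rose 11.7-fold to 7710 ± 697 from 677 ± 205 (SD, n = 3 and 3; log2 change 3.55 ± 0.32, adjusted p = 1.93e-05). GSP2, a Ran GTPase gene, rose 11.03-fold (3.46 ± 0.42), RTC3 9.53-fold (3.25 ± 0.32) and the vacuolar aminopeptidase gene APE1 8.32-fold (3.06 ± 0.35). ATG33, AIM17, STF1 and SNO1 rose by 2.90 to 2.96. MF(ALPHA)2 fell 12.0-fold (-3.59 ± 0.43, adjusted p = 0.000101), SAG1 5.99-fold (-2.58 ± 0.29) and STE3 4.99-fold (-2.32 ± 0.20), and the snoRNA gene SNR67 fell 5.61-fold (-2.49 ± 0.43).

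Ribosome biogenesis and RNA polymerase I genes fell in 69 of 74 cases and 5 were not called, with 72 falls adjusted over the list alone (median -0.95, adjusted p = 1.61e-23, and adjusted p = 0.182 with an estimated correlation). UTP22, a processome gene, and RPA190, the largest RNA polymerase I subunit gene, changed by -1.58 ± 0.17 and -1.43 ± 0.18. All 10 PAU genes rose, also adjusted over the list alone (median 1.62, adjusted p = 2.35e-13, and adjusted p = 0.151 with an estimated correlation). Stress genes rose in 26 of 37 cases, 30 adjusted over the list alone (median 1.30, adjusted p = 3.09e-15, and adjusted p = 0.222 with an estimated correlation). Of 39 genes of the TCA cycle and respiratory chain 14 rose and 25 were not called, also adjusted over the list alone (median 0.36, adjusted p = 8.29e-05, and adjusted p = 0.432 with an estimated correlation). Sulfur and methionine genes rose in 8 of 27 cases, 10 adjusted over the list alone (median 0.66, adjusted p = 8.48e-05, and adjusted p = 0.394 with an estimated correlation). MET17, a homocysteine synthase gene, changed by 2.26 ± 0.39. Alpha-specific genes fell in 4 of 5 cases, also adjusted over the list alone (median -2.32, adjusted p = 6.88e-05, and adjusted p = 0.151 with an estimated correlation). Of 24 genes of the G2/M list 7 fell, also adjusted over the list alone (median -0.39, adjusted p = 0.00623, and adjusted p = 0.394 with an estimated correlation). MCM7, MCM3 and MCM6, which encode subunits of the replicative helicase, changed by -1.20, -0.84 and -0.89.

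The H3 lysine substitution changed 2004 probe sets, 925 higher and 1079 lower. The larger share turned to higher under quantile normalization (1073 and 1007) and median centring (1087 and 940). A block for the sampling period left 677, of which 597 were among the 2004, with medians of -0.70 for ribosome biogenesis and 1.53 for PAU genes. That block sets the group against the third wild-type array alone, the one whose header named an amplification kit, and so does the block for chip lot, chosen after seeing the data, which left 410.

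In the H4 tail deletion, OLI1, the ATP synthase subunit gene of the mitochondrial genome, read 2.7 on both arrays against 21900 ± 414 in wild type (SD, n = 3), at least 156-fold lower (adjusted p = 4.89e-11). MF(ALPHA)2 fell 50.7-fold and MF(ALPHA)1, the main alpha-factor gene, 40.9-fold, to 651 ± 68.8 from 27841 ± 10878 (log2 change -5.35 ± 0.29, adjusted p = 8.44e-08). FAR1 fell at least 27.1-fold (-4.76 ± 0.26), while FUS3, a kinase gene of the mating pathway, and STE18, a G protein gene, reached the floor and were at least 8.08-fold and 7.97-fold lower, with means of 38.4 and 64.2 against 1159 and 1147. HMRA1, the a1 repressor gene of a silent mating-type locus, rose at least 4.72-fold, with means of 718 ± 362 and 86.0 ± 52.5 and 2 of 3 wild-type arrays at the floor (2.24 ± 0.23, adjusted p = 3.82e-05). Its probe set is of a kind that can bind several transcripts, and HMRA1 was the 1 silent mating-type gene tested. RTC3 rose 14.6-fold, DPI8 11.7-fold, TMA10 11.3-fold, APE1 10.8-fold and the hexokinase gene HXK1 10.6-fold.

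All 14 haploid-specific genes, which a1 with alpha2 represses in diploid cells, fell, also adjusted over the list alone (median -2.35, adjusted p = 6.34e-12, and adjusted p = 0.0288 with an estimated correlation). So did all 5 alpha-specific genes, also adjusted over the list alone (median -3.66, adjusted p = 3.36e-08, and adjusted p = 0.0288 with an estimated correlation). Of 74 ribosome biogenesis and RNA polymerase I genes 70 fell, 72 adjusted over the list alone (median -1.26, adjusted p = 6.39e-28, and adjusted p = 0.119 with an estimated correlation). RRP5 and LSG1, assembly factor genes, changed by -2.01 ± 0.23 and -2.00 ± 0.23. Iron regulon genes rose in 14 of 23 cases and 1 fell, also adjusted over the list alone (median 0.94, adjusted p = 1.86e-07, and adjusted p = 0.227 with an estimated correlation). The cell-wall genes FIT3 and FIT2 changed by 2.93 ± 0.38 and 2.48 ± 0.34. Stress genes rose in 27 of 37 cases, 29 adjusted over the list alone (median 1.65, adjusted p = 7.06e-15, and adjusted p = 0.233 with an estimated correlation), and PGM2, a phosphoglucomutase gene, changed by 3.24 ± 0.32. All 10 PAU genes rose, also adjusted over the list alone (median 1.44, adjusted p = 8.5e-11, and adjusted p = 0.108 with an estimated correlation). Of 27 sulfur and methionine genes 10 rose, 13 adjusted over the list alone (median 0.72, adjusted p = 3.95e-05, and adjusted p = 0.393 with an estimated correlation).

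The H4 tail deletion changed 2145 probe sets, 963 higher and 1182 lower, or 1154 and 1087 under median centring. With the day as a block 403 were called, 337 of them among the 2145, and the haploid-specific, alpha-specific and ribosome biogenesis medians were -1.94, -2.90 and -1.11. That block links 1 array of this group on day A to 1 wild-type array on day B through other mutants. With a block for chip lot the group counts through its second array alone, since no lot is given for the first. The count was 1111 without the second and 1314 without the first H4 tail deletion array, 1120 without the 3 arrays whose headers named another strain, and 1067 with a block for chip lot.

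With H4 lysines changed to glutamine, RTC3 rose 9.97-fold to 2592 ± 357 from 276 ± 138 (SD, n = 2 and 3; log2 change 3.32 ± 0.35, adjusted p = 7.38e-05). The glycogen phosphorylase gene GPH1 rose 9.95-fold (3.32 ± 0.52), HXK1 9.44-fold (3.24 ± 0.73), HXT4 8.49-fold (3.09 ± 0.53) and TSL1, a trehalose synthase subunit gene, 8.16-fold (3.03 ± 0.52). FIT2 fell 5.91-fold (-2.56 ± 0.34, adjusted p = 0.000267), CGR1, a ribosome biogenesis gene, 5.30-fold (-2.41 ± 0.36) and RKI1, a pentose phosphate enzyme gene, 4.67-fold (-2.22 ± 0.34). HMRA1 rose at least 2.05-fold, to 291 ± 24.6 (1.03 ± 0.23, adjusted p = 0.00571).

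Stress genes rose in 30 of 37 cases and 7 were not called, also adjusted over the list alone (median 1.74, adjusted p = 5.53e-21, and adjusted p = 0.16 with an estimated correlation), such as DDR2 (2.35 ± 0.17) and the chaperone gene SSA4 (2.65 ± 0.27). Ribosome biogenesis and RNA polymerase I genes fell in 68 of 74 cases, 71 adjusted over the list alone (median -1.28, adjusted p = 5.85e-26, and adjusted p = 0.16 with an estimated correlation). NOP7, a large-subunit assembly gene, changed by -2.00 ± 0.20. All 10 PAU genes rose, also adjusted over the list alone, by a median of 2.00 (adjusted p = 4.3e-15, and adjusted p = 0.112 with an estimated correlation). Of 14 haploid-specific genes 10 fell and 4 were not called, with 11 falls adjusted over the list alone (median -1.23, adjusted p = 7.93e-06, and adjusted p = 0.16 with an estimated correlation). The G protein genes GPA1 and STE4 changed by -1.75 ± 0.24 and -1.54 ± 0.22. Glycolytic genes rose in 6 of 19 cases, also adjusted over the list alone (median 0.42, adjusted p = 3e-06, and adjusted p = 0.365 with an estimated correlation), led by the glucokinase gene GLK1 (2.62 ± 0.38).

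The H4 lysine substitution changed 1974 probe sets, 682 higher and 1292 lower, or 1085 and 1030 under median centring. A block for the sampling period left 615, of which 552 were shared, with medians of 1.60 for stress, -0.98 for ribosome biogenesis and 1.86 for PAU genes, and a block for chip lot left 93. In both blocks the third wild-type array alone stands for wild type. The count was 824 without the first and 1286 without the second array of this group.

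**Figure D2:**
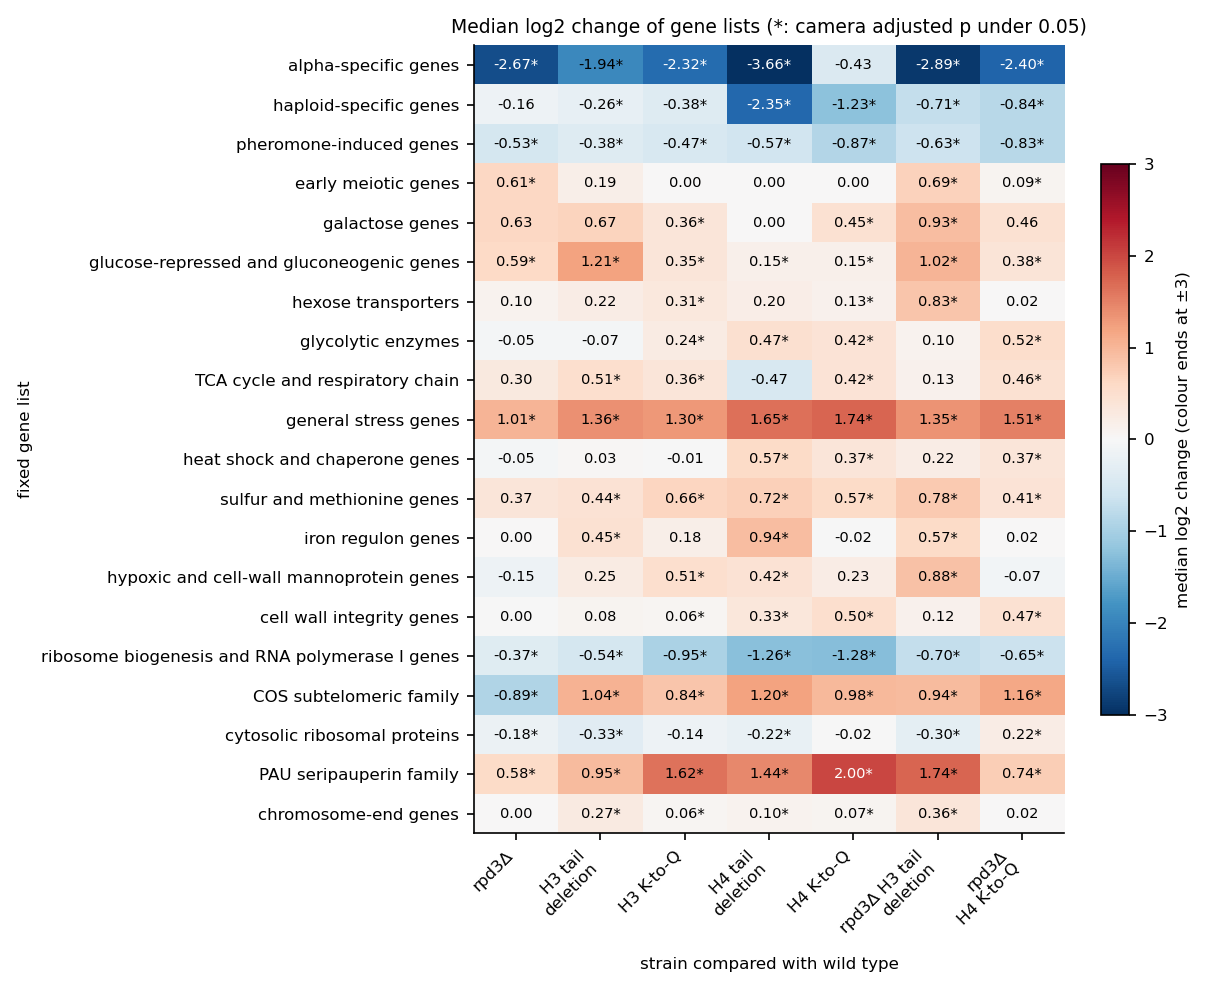
Median log2 change (colour and number) of gene lists fixed in advance, each mutant against wild type, for the lists called in at least 3 of the 7 comparisons, with an asterisk where camera passed at the preset correlation. Ribosome biogenesis genes run from -0.37 to -1.28 and stress genes from 1.01 to 1.74, while COS genes read -0.89 in the RPD3 deletion and 0.84 to 1.20 in the other 6 groups, a call lost under quantile normalization in the H3 lysine substitution, where median centring lost it too, and in the H4 double mutant.

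In the double mutant of RPD3 and the H3 tail, SRX1, the sulfiredoxin gene, rose 12.0-fold to 2826 ± 337 from 249 ± 103 (SD, n = 2 and 3; log2 change 3.59 ± 0.27, adjusted p = 2.43e-06), and the sporulation glucoamylase gene SGA1 rose 11.1-fold (3.47 ± 0.18, adjusted p = 9.56e-08). The snoRNA genes SNR128 and SNR13 rose 13.3-fold and 10.6-fold (3.73 ± 0.89 and 3.41 ± 0.49). MF(ALPHA)2 fell 40.5-fold (-5.34 ± 0.48), AFB1 12.8-fold (-3.67 ± 0.19), INA1 11.7-fold (-3.55 ± 0.22) and PRM4, a pheromone-regulated gene, 8.48-fold (-3.08 ± 0.32). RDN25-1, which encodes 25S ribosomal RNA, rose by 3.95 ± 1.28 (adjusted p = 0.0391), a call lost in other settings, such as the actin ratio as a covariate (3.54, adjusted p = 0.128). Its other probe set had the opposite sign.

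All 5 alpha-specific genes fell, also adjusted over the list alone (median -2.89, adjusted p = 6.68e-09, and adjusted p = 0.0409 with an estimated correlation). Early meiotic genes rose in 14 of 22 tested cases and 8 were not called, also adjusted over the list alone (median 0.69, adjusted p = 5.29e-06, and adjusted p = 0.132 with an estimated correlation), among them DMC1 and IME2, a meiotic kinase gene (2.32 ± 0.27 and 2.08 ± 0.26). Of 27 glucose-repressed and gluconeogenic genes 15 rose, or 16 with 1 fall adjusted over the list alone (median 1.02, adjusted p = 1.61e-07, and adjusted p = 0.132 with an estimated correlation). The carnitine genes CAT2 and CRC1 changed by 2.49 and 2.45. Of 17 hypoxic and cell-wall mannoprotein genes 10 rose and 1 fell, or 12 and 2 adjusted over the list alone (median 0.88, adjusted p = 0.000436, and adjusted p = 0.132 with an estimated correlation). All 10 PAU genes rose, also adjusted over the list alone (median 1.74, adjusted p = 2.96e-10, and adjusted p = 0.132 with an estimated correlation). Genes of ribosome biogenesis and RNA polymerase I fell in 37 of 74 cases, 50 adjusted over the list alone (median -0.70, adjusted p = 1.12e-17, and adjusted p = 0.132 with an estimated correlation).

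This double mutant differed from wild type in 1849 probe sets, 1211 higher and 638 lower. The split was 1028 and 1019 under quantile normalization and 880 and 1183 under median centring, which moved the median of all genes to -0.12. With the day as a block and 1 wild-type array in it, 952 were called, with medians of -2.97, 0.71 and 1.49 for alpha-specific, early meiotic and PAU genes.

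In the double mutant of RPD3 and the H4 lysines, OPI3 rose 12.1-fold to 16938 ± 1401 from 1502 ± 731 (SD, n = 2 and 3; log2 change 3.60 ± 0.37, adjusted p = 6.44e-05), INO1 9.96-fold (3.32 ± 0.35) and GSP2 12.6-fold (3.66 ± 0.47). RDN25-1 was called higher (5.14 ± 1.28, adjusted p = 0.011), with 16752.1 and 18944.5 against 322.1, 161.7 and 2489 in wild type. The change was 6.29 without the third and 4.31 without the second wild-type array. The call was lost without the first or second array of the double mutant (5.23 and 5.05). It was also lost with a block for period (2.84) or for chip lot (4.37). The H4 lysine substitution alone read 12246.9 and 395.3. SST2 fell 9.08-fold (-3.18 ± 0.26, adjusted p = 1.27e-05), MF(ALPHA)2 8.43-fold (-3.08 ± 0.48), STE3 7.01-fold (-2.81 ± 0.22) and the sterol esterase gene YEH1 6.30-fold (-2.66 ± 0.28). NUP170 was called lower (-2.86 ± 0.49), with 1 of its 5 other probe sets of opposite sign.

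Of 5 alpha-specific genes 4 fell, also adjusted over the list alone (median -2.40, adjusted p = 0.000304, and adjusted p = 0.377 with an estimated correlation). Pheromone-induced genes fell in 9 of 15 cases, also adjusted over the list alone (median -0.83, adjusted p = 6.8e-05, and adjusted p = 0.377 with an estimated correlation). The fusion genes FUS1 and FIG1 changed by -2.47 ± 0.28 and -2.45 ± 0.41. Stress genes rose in 25 of 37 cases, 28 adjusted over the list alone (median 1.51, adjusted p = 1.6e-12, and adjusted p = 0.377 with an estimated correlation). Of 16 phospholipid and inositol genes 5 rose, 6 adjusted over the list alone (median 0.21, adjusted p = 0.00579, and adjusted p = 0.377 with an estimated correlation). Of the ribosome biogenesis and RNA polymerase I genes, 36 of 74 fell, or 43 adjusted over the list alone (median -0.65, adjusted p = 1.43e-11, and adjusted p = 0.441 with an estimated correlation).

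This double mutant differed from wild type in 1925 probe sets, 913 higher and 1012 lower. A block for the sampling period left 621, of which 547 were shared, with medians of -2.56 for alpha-specific and 1.32 for stress genes, and a block for chip lot left 157. Both rest on the third wild-type array alone. The count was 724 and 962 without the first or second array of the double mutant and 1271 without the second wild-type array.

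Deleting RPD3 in cells that already lacked the H3 tail raised the meiotic kinase gene IME2 (1.37 ± 0.28, adjusted p = 0.029). LEU2, a leucine biosynthesis gene often used as a marker, read 4.81-fold higher on 1 of its 3 probe sets, at 4303 ± 715 against 901 ± 206 (SD, n = 2 and 2; 2.27 ± 0.27). Whether this signal came from a marker was not tested. AFB1 fell 4.27-fold (-2.10 ± 0.21, adjusted p = 0.00014) and MF(ALPHA)1 3.11-fold (-1.64 ± 0.31, adjusted p = 0.0218). RPD3 was at least 5.86-fold lower, and the snoRNA gene SNR45 at least 5.52-fold higher, with means of 821 and 73.9. Of 22 early meiotic genes 3 rose, 10 adjusted over the list alone (median 0.49, adjusted p = 2.08e-08, and adjusted p = 0.0574 with an estimated correlation), and of 5 alpha-specific genes 2 fell, 4 adjusted over the list alone (median -1.64, adjusted p = 1.63e-06, and adjusted p = 0.0574 with an estimated correlation). None of 10 PAU genes was called on its own, though 8 were higher adjusted over the list alone (median 0.74, adjusted p = 2.08e-08, and adjusted p = 0.195 with an estimated correlation). The contrast called 105 probe sets, 84 higher and 21 lower (60 and 28 under median centring). Without the second or the first array of the H3 tail deletion 44 and 55 were called.

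Deleting RPD3 in the H4 lysine substitution raised FIT2, an iron-linked cell-wall gene, 6.29-fold to 1489 ± 42.9 from 242 ± 73.6 (SD, n = 2 and 2; 2.65 ± 0.37, adjusted p = 0.0032), and the acid phosphatase gene PHO5 4.82-fold (2.27 ± 0.48, adjusted p = 0.0219). MF(ALPHA)2 fell 8.44-fold (-3.08 ± 0.52, adjusted p = 0.00788) and STE3 5.19-fold (-2.38 ± 0.25), and RPD3 was at least 4.72-fold lower. Of 10 PAU genes 9 fell, and 10 adjusted over the list alone (median -1.23, adjusted p = 4.2e-17, and adjusted p = 0.0674 with an estimated correlation). Ribosome biogenesis and RNA polymerase I genes rose in 9 of 74 cases, 30 adjusted over the list alone (median 0.60, adjusted p = 6.04e-13, and adjusted p = 0.427 with an estimated correlation), among them NOP8 (1.82 ± 0.28) and NOP7 (1.26 ± 0.22). Stress genes fell in 3 of 37 cases, also adjusted over the list alone (median -0.45, adjusted p = 5.73e-05, and adjusted p = 0.754 with an estimated correlation), namely HSP12, PGM2 and GRE1. This contrast lay within 1 day and 1 chip lot and called 268 probe sets, 170 higher and 98 lower. The split was 141 and 171 under quantile normalization and 117 and 251 under median centring. This contrast called more probe sets with day as a block, fixed or random. Leaving out any of its 4 arrays left 93, 61, 58 or 87.

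The interaction with the H3 tail deletion called 407 probe sets, 99 higher and 308 lower. CRG1, COX5B and CYC7 had interactions of -3.94 ± 0.49, -3.89 ± 0.53 and -3.62 ± 0.61 (adjusted p = 0.00263, 0.00263 and 0.00706), and FUS1 and SAG1 of 3.18 ± 0.42 and 3.13 ± 0.48 (adjusted p = 0.00263 and 0.00453). Stress genes were lower in 8 of 37 cases, 16 adjusted over the list alone (median -1.18, adjusted p = 4.46e-08, and adjusted p = 0.77 with an estimated correlation). OPI3 and INO1 were lower than additive by -2.90 ± 0.55 and -2.57 ± 0.52. With the day as a block, and wild type present through 1 array, 117 probe sets were called, 59 higher and 58 lower, and the stress median was -0.91. The split was 59 higher and 27 lower without the 3 arrays whose headers named another strain, and 78 and 94 without the second double mutant array. With the actin ratio as a covariate 227 were called, 52 higher and 175 lower. The count ran from 149 without the second RPD3 deletion array to 778 without the first array of the double mutant.

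The interaction with the H4 lysine substitution called 248 probe sets, 76 higher and 172 lower. CYC7, COX5B and the ribonucleotide reductase gene RNR3 had interactions of -3.48 ± 0.61, -3.36 ± 0.53 and -2.99 ± 0.49 (adjusted p = 0.00937, 0.00574 and 0.0068), and FIT2 of 3.74 ± 0.50 (adjusted p = 0.00323). Of 74 ribosome biogenesis and RNA polymerase I genes 16 were higher, 46 adjusted over the list alone (median 0.98, adjusted p = 1.76e-27, and adjusted p = 0.219 with an estimated correlation). PAU genes were lower in 9 of 10 cases, 10 adjusted over the list alone (median -1.74, adjusted p = 2.47e-15, and adjusted p = 0.107 with an estimated correlation), and stress genes in 10 of 37, 23 adjusted over the list alone (median -1.36, adjusted p = 4.66e-17, and adjusted p = 0.219 with an estimated correlation). Medians with the day as a block were 0.79, -1.46 and -0.97 for these 3 lists, with 101 probe sets called and wild type present through 1 array. The actin ratio as a covariate left 109 calls, 23 higher and 86 lower. The count ran from 80 without the second H4 lysine substitution array to 434 without the first wild-type array.

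Between the 2 H3 mutants, PCK1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was 5.75-fold higher in the tail deletion, at 7448 ± 2062 against 1285 ± 244 (SD, n = 2 and 3; 2.52 ± 0.41, adjusted p = 0.0224), and the snoRNA genes SNR67, SNR61 and SNR66 were higher by 2.44, 2.41 and 2.40. Of 27 glucose-repressed and gluconeogenic genes 1 was called higher, 9 adjusted over the list alone (median 0.62, adjusted p = 0.000112, and adjusted p = 0.485 with an estimated correlation). None of 10 PAU genes was called on its own, and 7 were lower adjusted over the list alone (median -0.72, adjusted p = 7.97e-11, and adjusted p = 0.275 with an estimated correlation). The contrast called 31 probe sets, 28 higher and 3 lower, with 1502 at an unadjusted p under 0.05. Without replicates 1, 2 and 3 of the H3 lysine substitution in turn, 10, 3 and 3 were called. The median of all genes was 0.14, and the split was 5 and 6 under quantile normalization and 16 and 53 under median centring. With the period as a block, which links the 2 groups through the wild-type arrays alone, 9 were called.

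Between the 2 H4 mutants, FIT2 was 32.9-fold higher in the tail deletion, at 7792 ± 689 against 242 ± 73.6 (SD, n = 2 and 2; 5.04 ± 0.37, adjusted p = 4.05e-06), and FET3, a ferroxidase gene, 11.9-fold (3.57 ± 0.71). OLI1 was at least 143-fold lower, MF(ALPHA)1 was 47.2-fold lower (-5.56 ± 0.31, adjusted p = 1.94e-07) and FAR1 at least 9.34-fold lower (-3.22 ± 0.29), while HMRA1 was 2.31-fold higher (1.21 ± 0.25, adjusted p = 0.0142). All 5 alpha-specific genes were lower, also adjusted over the list alone (median -2.73, adjusted p = 1.83e-14, and adjusted p = 0.00563 with an estimated correlation). Of 39 genes of the TCA cycle and respiratory chain 16 were lower and 1 higher, or 25 and 2 adjusted over the list alone (median -0.84, adjusted p = 7.19e-15, and adjusted p = 0.293 with an estimated correlation), among them COX4 (-1.99 ± 0.33) and COX5A (-1.68 ± 0.27). Against wild type this list was not called in the tail deletion (median -0.47, adjusted p = 0.0941) and was higher in the lysine substitution (median 0.42, adjusted p = 1.05e-05, and adjusted p = 0.44 with an estimated correlation). Iron regulon genes were higher in 11 of 23 cases, 14 adjusted over the list alone (median 0.85, adjusted p = 4.92e-12, and adjusted p = 0.1 with an estimated correlation). The contrast called 428 probe sets, 285 higher and 143 lower, a split of 280 and 229 under quantile normalization and of 282 and 261 under median centring. A block for the period, linked in the same way, left 69 and a block for chip lot 62, and leaving out any of the 4 arrays left 113 to 152.

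Genes near chromosome ends were called higher more often than others in every mutant but the RPD3 deletion. As a set, the chromosome-end list was called neither in the RPD3 deletion nor in the H4 double mutant. Genes of other lists, such as the subtelomeric COS family, were not taken out of it. In the H3 double mutant 44.1% of the 161 genes ranked 1 to 5 from an end, among tested genes, rose against 14.8% of 4345 genes ranked beyond 30. The shares were 28.0% and 11.9% in the H3 tail deletion, 28.6% and 11.9% in the H4 tail deletion, and 9.32% and 14.6% in the RPD3 deletion. They were 22.4% and 13.0% in the H3 lysine substitution, 23.0% and 7.04% in the H4 lysine substitution, and 18.6% and 9.80% in the H4 double mutant. A gene under the floor in wild type was tested only if at least 2 mutant arrays were above it, and could not be called lower. Such genes add to the shares that rose, and how many lay near the ends was not counted. Of the 321 tested genes of the chromosome-end list 118 rose and 15 fell in the H3 double mutant, 128 and 18 adjusted over the list alone (median 0.36, adjusted p = 1.97e-06, and adjusted p = 0.132 with an estimated correlation). The H3 lysine substitution, the H4 tail deletion and the H4 lysine substitution had 71, 85 and 64 rises with 26, 29 and 38 falls (medians 0.06, 0.10 and 0.07, adjusted p = 0.00112, 0.00103 and 0.00405, and adjusted p = 0.372, 0.329 and 0.39 with an estimated correlation). In the H3 tail deletion 77 rose and 3 fell, 85 and 7 adjusted over the list alone (median 0.27, adjusted p = 3.35e-05, and adjusted p = 0.265 with an estimated correlation). YPS6, a cell-wall protease gene, changed by 2.48 ± 0.19 and 2.17 ± 0.19 in these 2 groups, and the falls in the double mutant included RPD3 itself. A block for the day gave medians of 0.29 and 0.17. Median centring kept the 5 calls but changed the order of the groups, with medians of 0.17 in the H3 double mutant, 0.12 in the H3 tail deletion, 0.13 in the H3 lysine substitution, 0.19 in the H4 tail deletion and 0.21 in the H4 lysine substitution.

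**Figure D3:**
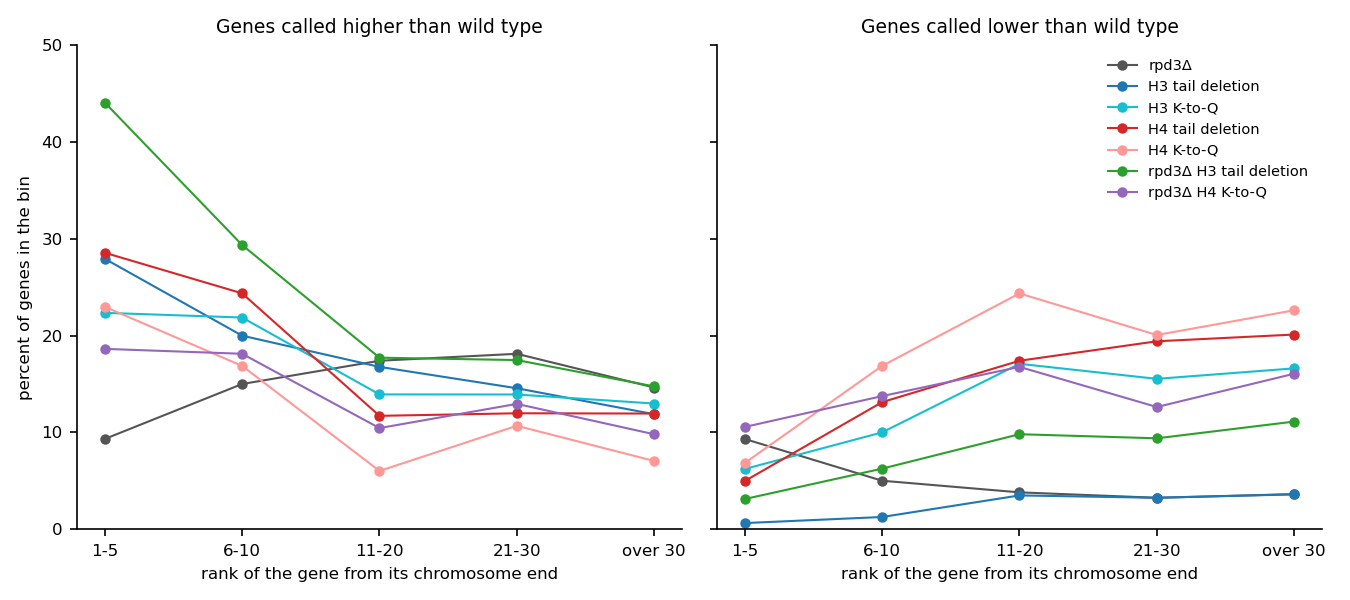
Percent of genes called higher (left) or lower (right) than wild type, by rank of the gene from its chromosome end among tested genes, for the 7 mutants (lines). The H3 double mutant reaches 44.1% at ranks 1 to 5, and the RPD3 deletion reads 9.32% there.

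Control probe sets for ribosomal RNA, which took no part in the comparisons, varied widely. Over 5 probe sets, the geometric mean of 18S signal was 53.6 to 89.0 in wild type, 302.4 and 376 in the H3 double mutant, and 847.9 and 1196 in the H4 double mutant. The 25S signal was 51.7, 59.7 and 695.7 in wild type, 2714 and 139.6 in the H4 lysine substitution, and 2492 and 3533 in its double mutant. In the H3 double mutant it was 573.7 and 632.5, below the third wild-type array. Of 54 probe sets for snoRNAs, small RNAs that guide changes of ribosomal RNA, 17 rose in the H3 double mutant and 16 in the H4 double mutant. The RPD3 deletion had 4 such rises, the H3 tail deletion 0, the H3 lysine substitution 1 with 10 falls, the H4 tail deletion 9 and the H4 lysine substitution 5.

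**Figure D4:**
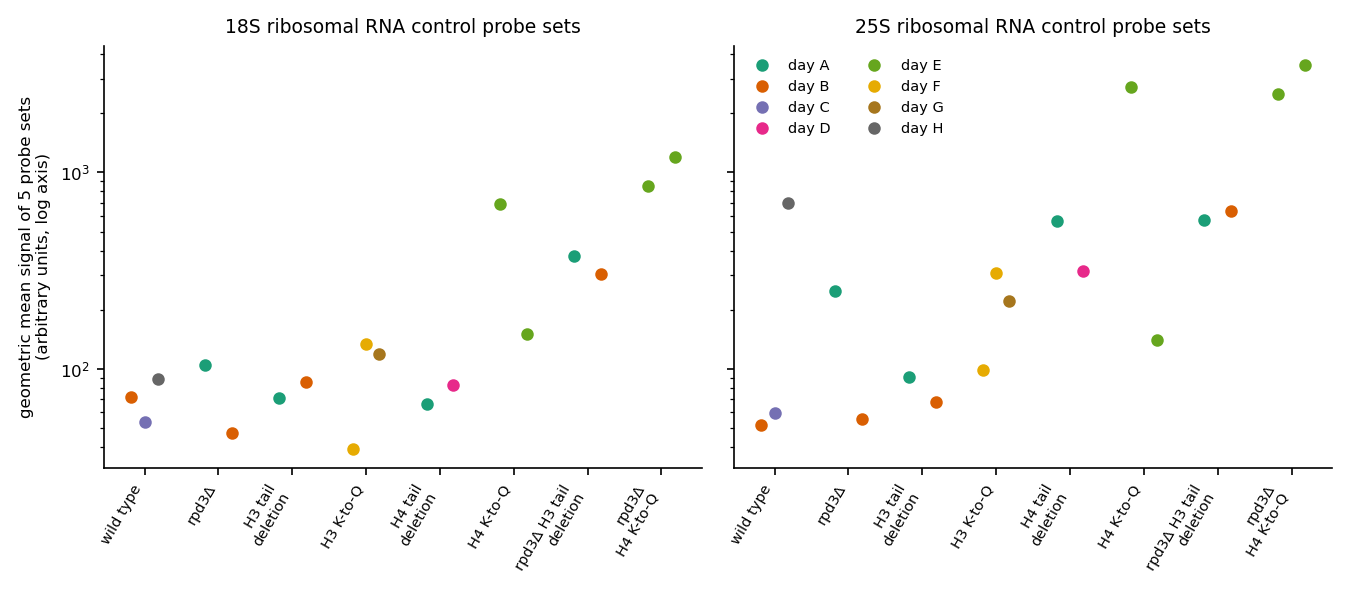
Geometric mean signal of the 5 probe sets each for 18S (left) and 25S (right) ribosomal RNA, per array (points, log axis, arbitrary units), by group and coloured by sampling day. The highest 25S values, 3533, 2714 and 2492, belong to 3 of the 4 arrays of day E.

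Changes in the RPD3 deletion correlated across probe sets, which are not independent replicates, with those in the H3 tail deletion (r = 0.65) and the H3 lysine substitution (0.56) and with those in the H4 tail deletion (0.38) and the H4 lysine substitution (0.25). All comparisons share 3 wild-type arrays. Sharing 3 arrays gave 0.40, 0.45, 0.40 and 0.40 in simulations of unchanged groups. These drew every array anew, wild type included, with a spread per probe set pooled over the groups and without effects of day or lot. Covariances exceeded the simulated ones by 0.214, 0.200, 0.154 and 0.0767. These excesses are too large if wild type varied more than the pooled spread. The lowest correlation within any group, 0.949, was between 2 wild-type arrays. For the RPD3 deletion and the H3 tail deletion 506 probe sets rose and 81 fell in both, and 20 moved oppositely. Under quantile normalization 424 rose and 168 fell in both. Unchanged groups shared 0 calls on average in the simulations, which follows from their holding no effects, so it gives no measure for these counts. Independent lists would share 94.1 and 9.66, which leaves out the shared controls. The H3 mutants correlated at 0.76 (601 rose and 194 fell in both) and the H4 mutants at 0.74 (428 and 778), with covariance differences of 0.261 and 0.371. With different wild-type arrays for the 2 comparisons, 1 against 2 in all 6 ways, the mean correlations of the RPD3 deletion were 0.42, 0.36, 0.24 and 0.11 in the same order. The last ran from -0.11 to 0.38. For the H3 mutants the mean was 0.52 and for the H4 mutants 0.57. Mean covariances of the RPD3 deletion were then 0.188, 0.174, 0.128 and 0.0504, against 0.249, 0.235, 0.189 and 0.112 with shared arrays. The covariance with the H4 lysine substitution ran from -0.0649 to 0.179. Mean covariances were 0.235 for the H3 mutants and 0.345 for the H4 mutants. Each split rests on a single wild-type array for 1 of the comparisons, so part of the excesses may still come from these arrays. Neither the simulations nor the splits deal with shared sampling days. The RPD3 deletion and the H3 tail deletion shared days A and B and their chip lots, and deviations of their first arrays correlated at 0.34. The H3 double mutant shared these days and lots too. Deviations of its first array correlated at -0.05 with the RPD3 deletion and at 0.28 with the H3 tail deletion. The H4 tail deletion shared day A with the RPD3 deletion, and the lysine substitutions shared no day with it. Shared days may thus add to the order of these values.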

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

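The tests of where the ribosomal RNA signal came from were chosen after the result was seen. The tests of the interactions between RPD3 and the histones, and of other splits of the arrays, were fixed before it.

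The effect of deleting RPD3 differed with the H3 tail, by a test of the interaction itself, at 407 probe sets. Of single genes, FUS1 (3.18), SAG1 (3.13), AGA1 (3.01), MF(ALPHA)2 (2.81), FIG2 (2.81), STE3 (1.71) and the ribosomal RNA genes RDN5-1 and RDN5-3 (4.73 and 3.56) lay above the sum of the single effects on the log2 scale. The 18S control signal was also high on both arrays of this double mutant (376 and 302.4, against 53.6 to 89.0 in wild type). Whether the RDN5 values have the same source, which for the controls stays open, was not tested. CRG1 (-3.94), COX5B (-3.89), CYC7 (-3.62), GPG1 (-3.56), OPI3 (-2.90), INO1 (-2.57), SDP1 (-2.51) and TFS1 (-2.40) lay below it. Among gene lists, the interaction had medians of 1.71 for alpha-specific, 0.58 for pheromone-induced, 0.83 for COS, 0.26 for ribosome biogenesis and 0.24 for cytosolic ribosomal protein genes. For MF(ALPHA)2 and STE3 the sum of the single effects lay under the floor of 140.2, to which such signals were set. Part of their interactions, and of the alpha-specific median, was thus fixed by the floor. The medians were -1.18 for general stress, -0.69 for TCA cycle and respiratory chain, -0.47 for glucose-repressed and -0.41 for phospholipid and inositol genes. None of these 9 lists passed with an estimated correlation, and general stress alone held its call in every setting. With the day as a block the alpha-specific, pheromone-induced, ribosome biogenesis, ribosomal protein, TCA cycle and glucose-repressed lists lost theirs, the ribosomal protein and glucose-repressed lists under quantile normalization too. The COS list lost its call without the first RPD3 deletion array or the first double mutant array, and the phospholipid list with the chip lot block and in other settings.

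The effect of deleting RPD3 also differed with the H4 lysine substitution, by the same kind of test, at 248 probe sets. FIT2 (3.74), PRM4 (2.46), AGA1 (2.22), REA1 (2.21), RRP12 (1.86), FUS1 (1.78) and RPA135 (1.51) lay above the sum of the single effects. CYC7 (-3.48), COX5B (-3.36), RNR3 (-2.99), EMI2 (-2.95), PGM2 (-2.80), SDP1 (-2.42), DMC1 (-2.35), PAU7 (-2.28), PAU15 (-2.02), MAL11 (-1.99), PAU23 (-1.88), AAC3 (-1.82) and POT1 (-1.76) lay below it. List medians above 0 were 1.61 for alpha-specific, 0.98 for ribosome biogenesis, 0.97 for COS, 0.66 for haploid-specific, 0.65 for pheromone-induced and 0.45 for cytosolic ribosomal protein genes. Those below 0 were -1.74 for PAU, -1.36 for general stress, -0.75 for galactose, -0.43 for glucose-repressed, -0.42 for early meiotic, -0.40 for TCA cycle and respiratory chain, -0.40 for sulfur and methionine, and -0.31 for hypoxic genes. None of these 14 lists passed with an estimated correlation, and the general stress, ribosome biogenesis, ribosomal protein and PAU lists held their calls in every setting. With the day as a block the alpha-specific, pheromone-induced, galactose, glucose-repressed, TCA cycle and hypoxic lists lost theirs. The haploid-specific and COS lists lost theirs without the first RPD3 deletion array, the early meiotic list with the higher floor and the sulfur and methionine list with the period block.

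Signal of the ribosomal RNA control probe sets, which no comparison used, lay above the wild-type arrays in 3 groups. For 18S the geometric mean was 323 in the H4 lysine substitution, 337 in the H3 double mutant and 1007 in the H4 double mutant, against 53.6 to 89.0 in wild type. For 25S it was 2967 in the H4 double mutant against 51.7 to 696 in wild type. Sampling day or chip lot as the only source is argued against by ranges of 25.3-fold, 12.2-fold and 6.3-fold in 25S signal within 3 sets of arrays that share day and lot. Each range rests on 1 array, a different one in each set, without which it is 1.42-fold, 1.31-fold and 2.32-fold. Genotype as the only source over all groups is argued against by arrays of 1 genotype that differed 19.4-fold in the H4 lysine substitution, on 1 day, and 13.5-fold in wild type and 4.45-fold in the RPD3 deletion, on different days. Genotype as the source within the 2 double mutants stays open, because their arrays differed by at most 1.42-fold. The highest other array of the day was near them on days A and E (0.918 to 1.3-fold), and on day B the double mutant array lay 9.3-fold above it. Carry-over of RNA without poly(A) tails that varied between samples stays open too: deviations of 25S and of snoRNA signal from their group means correlated at 0.12 over 18 arrays (permutation p = 0.725), or 0.04 without the 2 farthest arrays, which leaves both a weak link and none possible.

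The 6 arrays of wild type and the H3 lysine substitution make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 2004 probe sets by limma, the highest of the other splits called 0, and 1 split, the real one, called as many. Every other split mixes the 2 groups, so any difference between them enters the spread. The 0 thus gives no measure of false calls. The real split also largely parts the sampling periods, with all arrays of the H3 lysine substitution later and 2 of 3 wild-type arrays earlier. The period block left 677 probe sets, with the third wild-type array alone standing for wild type.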

How the results depend on the processing

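The block for chip lot, the runs without the arrays whose headers named another strain and the use of different wild-type arrays for 2 comparisons were tests chosen after the results were seen, and the other settings were fixed before. A list or named gene was counted as kept where its direction and call stayed, whatever the change in size. Of 174 list calls 90 held in every setting, with 285 weaker and 2428 kept values. Of 637 named-gene calls 254 held, with 1370 weaker, 6 stronger and 8760 kept values. None reversed with a call, and a list whose direction turned without a call was counted as weaker. Of counts and overlaps, 83 values moved and 172 did not. A count moved if it changed more than 1.5-fold. A correlation moved if it changed by at least its standard deviation over the runs without 1 array. Background correction was not run, because probe-level values were not analysed here, and a day block could not be estimated for 5 of 13 contrasts. The cause was not tested where a value moved, other than that a run without an array has fewer arrays.

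With a block for day, counts moved from 1207 to 472 (358 shared) for the RPD3 deletion, 1071 to 290 (215) for the H3 tail deletion, 2145 to 403 (337) for the H4 tail deletion and 1849 to 952 (767) for the H3 double mutant. They moved from 268 to 552 (244) for RPD3 within the H4 lysine substitution, 407 to 117 (74) for the H3 interaction and 248 to 101 (61) for the H4 interaction. Day as a random block gave 234 for RPD3 within the H3 tail deletion (105 without it), 663 within the H4 lysine substitution, 7 between the H3 mutants (31 without it) and 249 between the H4 mutants (428 without it).

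A block for period gave 677, 615 and 621 for the H3 lysine substitution, the H4 lysine substitution and the H4 double mutant, 9 between the H3 mutants and 69 between the H4 mutants. A block for chip lot gave 729 for the RPD3 deletion, 410 for the H3 lysine substitution, 1067 for the H4 tail deletion, 93 for the H4 lysine substitution and 157 for the H4 double mutant. It gave 152 for the H3 interaction, 7 between the H3 mutants and 62 between the H4 mutants. In the period and chip lot blocks, the third wild-type array alone stands for wild type beside the later groups, and in the fixed day block the day B array alone. The chip lot block also counts the H4 tail deletion through its second array alone. A block for replicate number moved the H3 mutant contrast alone, to 5. Deviations of arrays of the same number correlated at 0.34, -0.05, 0.28 and 0.05. In the groups of the first 3 values the number goes with day and chip lot.

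The actin 3'/5' covariate gave 742 for the RPD3 deletion, 227 and 109 for the H3 and H4 interactions and 8 between the H3 mutants. Quantile normalization gave 11 and median centring 69 between the H3 mutants. Quantile normalization also raised the probe sets that fell in both of 2 mutants, from 81 to 168 for the RPD3 and H3 tail deletions, 124 to 188 for the RPD3 and H4 tail deletions and 194 to 309 for the 2 H3 mutants. With different wild-type arrays, correlations with the RPD3 deletion moved to 0.42, 0.36, 0.24 and 0.11 for the H3 tail deletion, the H3 lysine substitution, the H4 tail deletion and the H4 lysine substitution, to 0.52 between the H3 mutants and to 0.57 between the H4 mutants. Without a filter 40 were called for RPD3 within the H3 tail deletion and 20 between the H3 mutants. Without the 3 arrays whose headers named another strain, counts were 455 for the H3 tail deletion, 1120 for the H4 tail deletion, 86 for the H3 interaction, 97 between the H3 mutants and 206 between the H4 mutants.

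Leaving out 1 array at a time gave 520 (without the second RPD3 deletion array) to 1245 for the RPD3 deletion, 431 (without the second H3 tail deletion array, and 673 without the first) to 1265 for the H3 tail deletion, and 1340 to 2320 for the H3 lysine substitution. It gave 1111 (without the second H4 tail deletion array, and 1314 without the first) to 2479 for the H4 tail deletion and 824 (without the first array of the group, and 1286 without the second) to 2470 for the H4 lysine substitution. The range was 1333 to 2054 for the H3 double mutant and 724 (without its first array, with 962 without its second and 1271 without the second wild-type array) to 2276 for the H4 double mutant. For RPD3 within the H3 tail deletion it was 44 (without the second H3 tail deletion array, with 55 without the first) to 140. Within the H4 lysine substitution, leaving out its first or second array gave 93 or 61, and the first or second array of the double mutant 58 or 87.

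The H3 interaction ran from 149 (without the second RPD3 deletion array) to 778 (without the first double mutant array). It also moved without the first wild-type array (638), the first and second H3 tail deletion arrays (262 and 154) and the second double mutant array (172). The H4 interaction ran from 80 (without the second H4 lysine substitution array) to 434 (without the first wild-type array). It was 95 without the second RPD3 deletion array, 134 without the first H4 lysine substitution array, and 103 and 84 without the first and second double mutant arrays. Between the H3 mutants the range was 3 to 27, with 3 without the second H3 tail deletion array and 10, 3 and 3 without replicates 1, 2 and 3 of the H3 lysine substitution. Between the H4 mutants it was 113 to 152, with 152 and 129 without the first and second H4 tail deletion arrays and 142 and 113 without those of the lysine substitution. List calls ran from 160 to 180. Chromosome-end medians ran from 0.18 to 0.35 in the H3 tail deletion, 0.01 to 0.15 in the H3 lysine substitution, 0.08 to 0.17 in the H4 tail deletion, 0.00 to 0.10 in the H4 lysine substitution and 0.31 to 0.42 in the H3 double mutant, with no call lost.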

Other observations

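All tests in this part that weigh explanations were chosen after the results were seen.

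On 1 of its 3 probe sets, LEU2, a leucine biosynthesis gene, read 3079.7 and 3301 in the RPD3 deletion, 4807.9 and 3796.6 in the H3 double mutant and 4993.3 and 4850 in the H4 double mutant. It read 1953.5, 1555.3 and 997.6 in wild type. On the other 2 probe sets the second RPD3 deletion array (520.1 and 807.4) was close to the highest wild-type array (493.4 and 786.5). The labels do not say which marker replaced RPD3, so whether this signal came from a marker was not tested. HO, the endonuclease gene of mating-type switching, read 46.1 and 71.8 in the H4 tail deletion against 600.7, 359.4 and 228.9 in wild type. COS9 fell in the H4 double mutant (-1.10 ± 0.25) where 4 of its 6 family members rose, a list call lost under quantile normalization.

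In the H4 tail deletion, OLI1 read 2.7 on both arrays, on the 1 of its 2 probe sets that was above the floor in wild type. A defect of the OLI1 probe set as the only source of low mitochondrial signal is argued against by the other probe sets of the mitochondrial genome. Of 27, 11 (40.7%) lay below all 16 other arrays on both H4 tail deletion arrays, against 4.79% of 6476 nuclear ones (Fisher exact test, p = 2.29e-08). The test counts probe sets, which were read on the same 2 arrays and are not independent. Its p thus measures no spread between cultures, and the OLI1 reading itself was not checked. Loss of part of the mitochondrial genome is a candidate explanation, but the nuclear genes of the TCA cycle and respiratory chain leave it open. Their median was -0.84 against the H4 lysine substitution, where the list itself was higher than in wild type (0.42), and against wild type it was -0.47 without a call (3 rose, 14 fell, adjusted p = 0.0941). Neither the DNA nor growth on a respiratory carbon source was measured, so whether the H4 tail or a chance loss in the cultures lay behind it stays open.

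Also in the H4 tail deletion, alpha-specific and haploid-specific genes fell while HMRA1 rose. The a1 protein made from the silent locus in cells that hold alpha2 is a candidate explanation that stays open. The fall of 14 of 14 haploid-specific genes is part of what is to be explained and so lends it no weight. MATa cells in the cultures are argued against by the 4 a-specific genes, of which 0 were called higher: MFA1 changed by 0.48 (adjusted p = 0.386), and BAR1 was lower (-1.17, adjusted p = 0.00322). Diploid cells of both mating types in place of haploid cells stay open too, because MF(ALPHA)1 at 2.34% of wild type would follow from either state. The header of the second of these 2 arrays named another strain than its label.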
